A study of Mus musculus with 4 samples.

How the data were processed

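Bulk RNA sequencing was carried out on B cells sorted from the cervical lymph nodes of 2 groups of mice, a control strain labelled BL/10 and a strain labelled NOD.B10, with 2 libraries in each group. Per the labels' protocols, cells were sorted straight into a storage buffer, total RNA was extracted with a Qiagen RNeasy kit, and libraries were made by a standard Illumina protocol. The authors deposited 1 table of read counts per gene symbol for all 4 libraries, with no normalisation. Per the submitters' processing notes, the tools used upstream included HISAT2 2.1.0, SAMtools 1.3, Subread 1.6.5 and featureCounts, and the genome build was mm10. The gene annotation, the strand setting and the treatment of reads with several alignments were not given in the sources used here. Genes that overlap, that have an antisense partner or that have near-identical copies therefore carry an uncertain count. This applies among the genes named below to Xist and Tsix, to the ribosomal protein genes and Gapdh, and to the Ly6, Trim, Oas, Ifit, Ifi200, Hspa1 and H2 families.

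The table held 23418 gene symbols, of which 6360 had 0 reads in every library. Total counts were 29372751 and 26150794 reads in the BL/10 libraries and 19328803 and 25375678 reads in the NOD.B10 libraries. All symbols named a gene, so none was left out of the library sizes. Columns were matched to samples by the library names in the labels. Symbols were matched to NCBI RefSeq genes of GRCm38.p6, the assembly that corresponds to mm10, 21570 of them directly and 1663 through a synonym, while 185 did not match. Coordinates are 1-based positions on that assembly. Only 2 immunoglobulin chain symbols and 0 symbols of the mitochondrial genome were among the genes, so immunoglobulin constant regions and mitochondrial transcripts were not analysed here.

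Groups were compared with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust dispersion, glmQLFTest, two-sided) in R 4.3.3, on the deposited counts, with TMM normalisation. The filter filterByExpr, with a minimum count of 10 and a minimum total of 15, left 13075 genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene is called when its adjusted p is under 0.05. Every adjusted p given for a gene comes from this test unless another is named. Levels are counts per 1000000 reads (CPM) over TMM-scaled library sizes, given as mean ± SD of 2 libraries. A standard error (SE) accompanies log2 fold changes, which are NOD.B10 over BL/10. This SE was derived from the test, as the size of the fold change without shrinkage over the square root of the F statistic. It can lie below counting error where a group had few reads. This holds for Trim12a, Bcl11b and Il18r1, with 9, 24 and 8 reads in NOD.B10. Where both libraries of a group had 0 reads, the fold change is a lower bound, computed against 3 reads over the group, which is 0.0541 CPM in BL/10 and 0.0671 CPM in NOD.B10. Where a group had 1 to 3 reads, the fold is given with a 95% interval for counting error. Intervals and limits of this kind cover counting error only.

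Gene lists were fixed before the data were examined: 37 lists with 758 entries on the IL-36 family, immune pathways, B cell subsets, cell maintenance and the other cell types that a lymph node sort could hold. Of these, 34 lists had at least 4 tested members and were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over those lists. Members were also counted with p-values adjusted over the list alone. Camera was repeated with the correlation estimated from the data, and fry, which tests each list by itself, was run as well. With the estimated correlation, 0 of the 34 lists were called and 3 had an unadjusted p under 0.05. Unlike the preset setting, it uses the few residual degrees of freedom left by 4 libraries in 2 groups. The interferon-stimulated list went from camera p = 1.97e-18 to p = 0.00868 although its estimated correlation was −0.00769, below the preset 0.01. A call lost in that setting therefore does not show that gene correlation made the call, and decides neither way. The genes named in the text follow a rule fixed at the same time: all members of the IL-36 list; the 10 highest and the 10 lowest log2 fold changes among called genes with an average log2 CPM of at least 3 and no overlap between groups, leaving out unnamed gene models; and up to 3 called members of each list with the smallest adjusted p, or up to 2 members by unadjusted p where a list had no call. The rule gave 106 genes, some of which are not reported here. Unnamed gene models made up 158 of the called genes. Any other gene in the text was picked after its values were seen.

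The procedure was tested on simulated counts for this comparison, drawn over 12837 genes. It recovered 30% of genes changed 1.5-fold, 68% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, 50 genes each, and 7.7% of the 207 simulated calls were genes that had not been changed. A planted gene list was called, and 0 of 32 lists without planted genes were. The simulated genes were drawn independently of each other, whereas ribosomal protein genes had an estimated correlation of 0.64 in the data. The simulation therefore gives no rate of false list calls where genes vary together. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (1 CPM in each library of a group and an average log2 CPM of 1), the replicate number of the titles as a block, non-robust dispersion, removal of the immunoglobulin genes, and each library left out in turn. Removal of Rn45s, the ribosomal RNA precursor, was added after seeing the data. In the closing section, adjacency of called genes was compared with 10000 random permutations and gene lists with each other by two-sided permutation tests of 100000, in Python 3.11.15 with NumPy 2.4.6, and Fisher's exact test in SciPy 1.17.1. The replicates of a group were not copies of the same library: the chi-square statistic per degree of freedom between them was 43.2 for BL/10 and 18.0 for NOD.B10.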

Results

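Gene expression was measured by RNA sequencing in B cells sorted from the cervical lymph nodes, the nodes that drain the salivary glands, of BL/10 control mice and NOD.B10 mice. NOD.B10 mice carry the H2 region of C57BL/10 on the autoimmune-prone NOD background and are used as a model of Sjögren's disease, in which lymphocytes infiltrate the salivary and lacrimal glands. Each strain was represented by 2 libraries, with total counts between 19328803 and 29372751 reads. The comparison asks which genes differ between B cells of the disease-prone and the control strain. The series concerns the IL-36 cytokines, so that family is reported in full. The labels do not say whether the libraries of a strain came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

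Of 13075 genes tested, 1986 (15.2%) were called, 857 higher and 1129 lower in NOD.B10 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Changes above 4-fold numbered 532 lower and 180 higher. The first principal component of log2 CPM separated the strains and held 79.7% of the variance, and the correlation across genes was 0.986 within BL/10, 0.982 within NOD.B10 and 0.93 to 0.931 between strains. Interferon-stimulated genes, T cell markers, cell cycle genes, age-associated B cell genes and a list of marginal zone and B-1 cell genes were lower in NOD.B10 by camera, and class II presentation genes were higher. In all, camera called 17 of the 34 lists tested, 16 lower and 1 higher, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. The estimated setting rests on few residual degrees of freedom, so calls lost in it here and below decide neither way. The list called higher, class II presentation, lost its call when any 1 library was left out (adjusted p from 0.0559 to 0.0724). Without the first NOD.B10 library, 586 genes were called higher and 1228 lower.

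Among called genes with an average log2 CPM of at least 3 and no overlap between the strains, unnamed gene models left out, Col6a4 (chromosome 9, 105990318 to 106096828), which encodes a collagen VI chain, had the highest fitted fold change. It had 0 reads in BL/10 and 113 ± 8.76 CPM (SD, n = 2) in NOD.B10, at least 2090-fold higher (adjusted p = 1.26e-10). Cpne4 (chromosome 9, 104566701 to 105034544), a copine, likewise had 0 reads in BL/10 and 75.4 ± 5.27 CPM in NOD.B10, at least 1390-fold higher (adjusted p = 2.94e-10). With 1 BL/10 library left out these bounds fell to 985-fold and 1110-fold for Col6a4 and to 657-fold and 738-fold for Cpne4. Nlrp1a on chromosome 11, an inflammasome sensor, rose from 0.286 ± 0.309 to 39.8 ± 3.49 CPM, a log2 fold change of 7.17 (SE 0.443, adjusted p = 2.1e-05). The other genes of this rank were Lrrc63, the lipid transporter gene Abcb4, the kinase gene Alpk1, the interferon-inducible Ifi204, Pianp, Atp9a and the cilium gene Cep290, with folds from 41 for Lrrc63 to 11.3 for Cep290.

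Among the genes with the lowest fold changes, Trim12a (chromosome 7, 104299893 to 104315558), of the TRIM antiviral family, fell from 96.4 ± 8.54 to 0.189 ± 0.121 CPM, 511-fold lower in NOD.B10 (log2 fold change −8.88, SE 0.255, adjusted p = 1.26e-10). Trim12a had 9 reads in NOD.B10, and this SE lies below their counting error. The antigen gene Ly6c2 on chromosome 15 was 255-fold lower, with a 95% counting interval of 84.4 to 1200. The T cell genes Themis, Cd8b1, Bcl11b and Il7r belonged to this group, with log2 fold changes of −7.80, −7.63, −6.83 and −6.49. Map7, Als2cl and Nsg2 also belonged to it, between 186-fold and 87.6-fold lower.

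**Figure D1:**
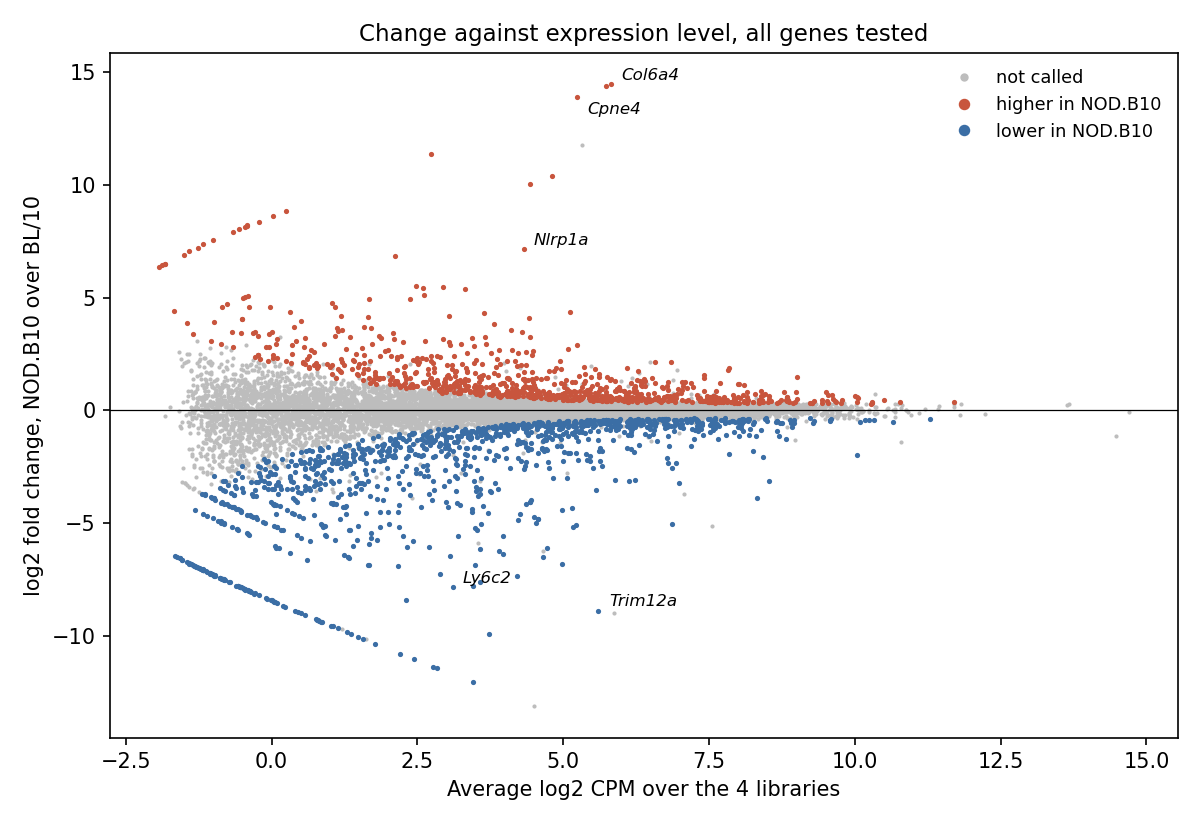
Log2 fold change of NOD.B10 over BL/10 (vertical axis) against the average log2 CPM over the 4 libraries (horizontal axis) for the 13075 genes tested, 1 point per gene, with the 1986 called genes coloured by direction. Col6a4 and Cpne4 stand near the top, and Trim12a and Ly6c2 lie at −8.88 and −7.85; the sloping lines at the edges are genes with 0 or few reads in 1 strain, whose fitted fold changes are not bounds.

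The IL-36 cytokine genes were hardly detected in either strain. Il1f6 (IL-36 alpha), Il1f8 (IL-36 beta) and Il1f5 (the IL-36 receptor antagonist), which lie on chromosome 2 between 24153172 and 24282432, had 0 reads in all libraries, which allows levels of up to 0.0541 CPM in BL/10 and 0.0671 CPM in NOD.B10. Il1f9 (IL-36 gamma) in the same cluster had 6 reads in the first BL/10 library and 0 in the others. Il1rl2 (chromosome 1, 40324589 to 40367555), the specific chain of the IL-36 receptor, had 17 and 36 reads in the BL/10 libraries and 0 in both NOD.B10 libraries, at least 14.7-fold lower (0.985 ± 0.581 CPM in BL/10, SD, n = 2, adjusted p = 0.00634). Its call was lost without the second BL/10 library (adjusted p = 0.0649), and the bound was 8.55-fold without that library, 20.8-fold without the first, and 8.33-fold and 6.34-fold without the first and second NOD.B10 library. T cell, mast cell and dendritic cell marker lists were called lower in the same NOD.B10 libraries, though not with an estimated correlation (adjusted p = 0.439, 0.439 and 0.526). Il1rap (chromosome 16, 26581509 to 26730128), the shared accessory chain of the receptor, stood at 20.9 ± 0.522 CPM in BL/10 and 28.2 ± 4.09 CPM in NOD.B10, a difference that was not called (log2 fold change 0.43, SE 0.166, adjusted p = 0.108). Adjusted over the list alone, 1 of the 2 tested members was lower and 1 higher.

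Of the other IL-1 family genes, 3 receptor genes were lower in NOD.B10. All 3 lie close to Il1rl2 on chromosome 1, between 40404864 and 40551707. The falls of these genes and of Il1rl2 may therefore not be separate results, and whether they share 1 cause was not tested. Il18r1, the IL-18 receptor chain, fell from 10.2 ± 3.52 to 0.182 ± 0.0358 CPM (log2 fold change −5.78, SE 0.474, adjusted p = 2.19e-06). Its partner chain Il18rap and the IL-33 receptor Il1rl1 were 39.7-fold and 46.4-fold lower, with 95% counting intervals of 9.08 to 284 and 9.5 to 2190. Il18rap lost its call without the second BL/10 library (adjusted p = 0.0521) and Il1rl1 without the first (adjusted p = 0.0647). Il18bp, the soluble IL-18 inhibitor, and Irak3, an inhibitor of the pathway, were higher with log2 fold changes of 0.80 and 0.43. Il18bp lost its call without the first BL/10 library (adjusted p = 0.086), and both lost it without the first NOD.B10 library (adjusted p = 0.186 and 0.217). These were 2 higher and 3 lower genes among 17 tested, or 2 and 4 adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.0596), except without the second BL/10 library (adjusted p = 0.0254) and with a replicate block (adjusted p = 0.0261). T cell markers were lower in the same libraries, as given below.

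Interferon-stimulated genes were lower in NOD.B10 as a group, in the same libraries in which 18 of 19 T cell markers and 6 of 7 natural killer cell markers were lower. Of 49 tested, 37 fell, 1 rose and 11 were not called, or 41 lower and 1 higher adjusted over the list alone, with a median log2 fold change of −1.11. Camera called the list lower (adjusted p = 4.25e-17), and adjusted p = 0.295 with an estimated correlation. Rsad2, which encodes the antiviral protein viperin, fell from 30.2 ± 7.84 to 0.631 ± 0.061 CPM, 47.9-fold (log2 fold change −5.58, SE 0.294, adjusted p = 3.55e-08). Oas3, a sensor of double-stranded RNA, fell from 58.8 ± 2.19 to 7.35 ± 0.31 CPM, 8-fold (adjusted p = 3.3e-08). Pydc4 of the Ifi200 family, the symbol under which Ifi213 was counted, was 15.8-fold lower (adjusted p = 2.75e-08). The 1 member that rose was Ifi204, also of the Ifi200 family, from 0.868 ± 0.0334 to 15.6 ± 1.53 CPM (adjusted p = 4.97e-07). Stat2, a transcription factor of the pathway picked out after its values were seen, was not called, with a log2 fold change of −0.13.

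Markers of T cells and of several other cell types were lower in NOD.B10, although the sort was for B cells. Of 19 T cell markers tested, 18 fell, or 19 adjusted over the list alone, with a median log2 fold change of −5.30. Bcl11b, a transcription factor of the T lineage, fell from 61.7 ± 6.25 to 0.552 ± 0.172 CPM (log2 fold change −6.83, SE 0.239, adjusted p = 9.53e-10). Tcf7 fell from 71.9 ± 12.2 to 2.17 ± 0.522 CPM, and the costimulatory receptor gene Cd28 from 30.2 ± 4.39 to 0.351 ± 0.0571 CPM. Of 10 follicular helper and regulatory T cell markers 7 fell, or 9 adjusted over the list alone, including Icos and Il2ra. Of 7 natural killer cell markers 6 fell, or 7 adjusted over the list alone, including Klrk1, at least 40.2-fold lower, or 17.4-fold to 54.3-fold with 1 library left out. Of 4 mast cell markers 3 fell, the same number adjusted over the list alone: Kit, Mcpt4 and Cpa3, each with 0 reads in NOD.B10, of which Cpa3 lost its call without the second BL/10 library (adjusted p = 0.0741). Of 5 erythroid markers 3 fell, or 4 adjusted over the list alone, including Slc4a1 and Alas2, the last losing its call without either BL/10 library (adjusted p = 0.278 and 0.259), with no filter (adjusted p = 0.102) and with a replicate block (adjusted p = 0.2). The camera adjusted p was 4.25e-17 for T cells, 1.97e-06 for the helper and regulatory list, 4.58e-06 for natural killer cells, 7.64e-05 for mast cells and 3.79e-04 for erythroid cells. For each of these 5 lists it was adjusted p = 0.439 with an estimated correlation. With genes at 0 reads set to their bound, the medians were −3.97 for mast cells and −5.62 for erythroid cells.

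Lists of macrophage and dendritic cell markers were also lower in NOD.B10 by camera. Of 14 macrophage and monocyte markers 3 fell (Apoe, Ccr2 and Csf1r), the same number adjusted over the list alone. Apoe, a lipid carrier, fell from 80.9 ± 0.144 to 17.1 ± 0.634 CPM (log2 fold change −2.24, SE 0.131, adjusted p = 8.08e-08). Of 11 dendritic cell markers 5 fell, or 6 lower and 1 higher adjusted over the list alone, including Itgax, Klk1 and Siglech of plasmacytoid cells. Camera called both lists lower (adjusted p = 0.00811 and 0.00616), each with adjusted p = 0.526 with an estimated correlation. The macrophage list lost its call without the second BL/10 library (adjusted p = 0.0978) and without the second NOD.B10 library (adjusted p = 0.0909), and Csf1r lost its call without either BL/10 library or the second NOD.B10 library (adjusted p = 0.0512, 0.0817 and 0.127). Of 6 neutrophil markers, Mmp9 and S100a8 fell, with 4 lower adjusted over the list alone (camera adjusted p = 0.0591). The list was called lower without the first BL/10 library (adjusted p = 0.00447), without the first NOD.B10 library (adjusted p = 0.0154) and with a replicate block (adjusted p = 0.015), and S100a8 lost its call without the second BL/10 library (adjusted p = 0.0562). The stromal and endothelial list was not called (adjusted p = 0.476), with 1 of 5 members higher both ways, Pdgfrb, which lost its call without the first BL/10 library (adjusted p = 0.0976) or the first NOD.B10 library (adjusted p = 0.0621). Of 9 salivary gland markers 1, Pip, passed the test for all genes and 0 did adjusted over the list alone, and the list was called lower at adjusted p = 0.0441 (adjusted p = 0.449 with an estimated correlation), which became 0.0503 with RLE factors, 0.0713 without the second BL/10 library, 0.101 with the stricter filter and 0.0516 without Rn45s, a setting added after the data were seen. Pip lost its call without either BL/10 library or the second NOD.B10 library (adjusted p = 0.243, 0.101 and 0.146), and with upper-quartile factors, DESeq2, limma-voom, a replicate block or non-robust dispersion (adjusted p from 0.0521 to 0.0891).

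**Figure D2:**
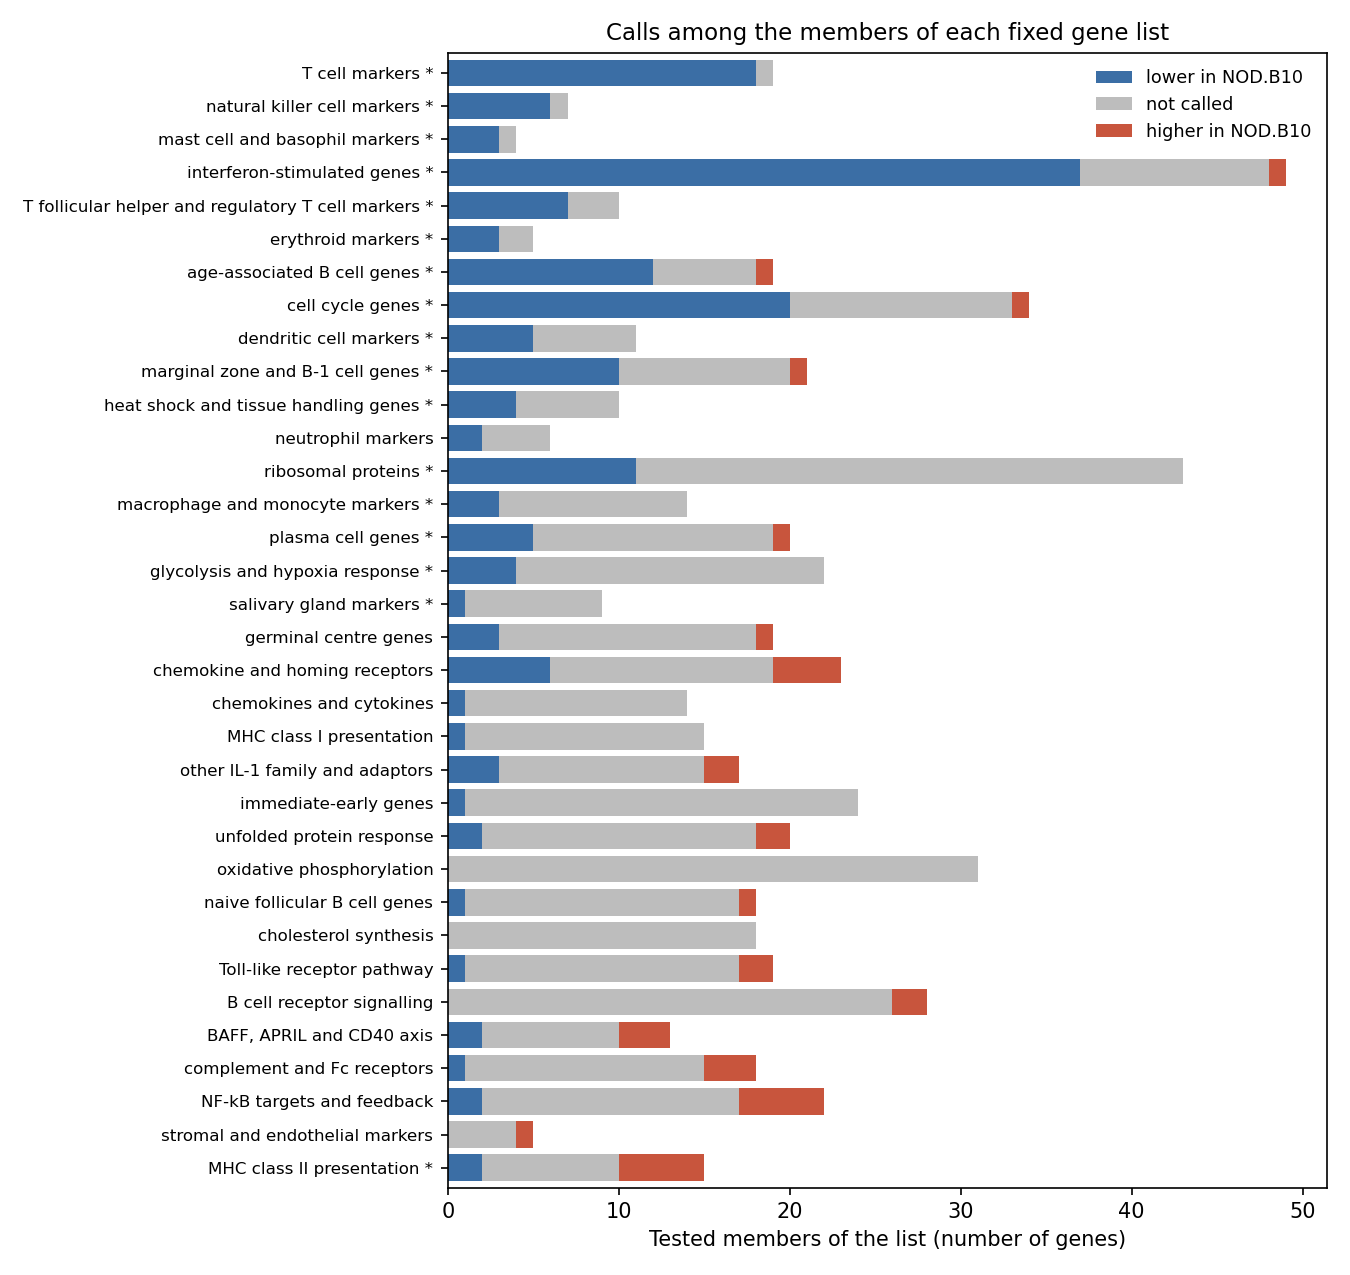
Number of tested members (horizontal axis) of each fixed gene list that were called lower in NOD.B10, not called, or called higher, for the 34 lists with at least 4 tested members, sorted by net share. A star marks lists called by camera with the preset correlation; 37 of 49 interferon-stimulated genes and 18 of 19 T cell markers were lower, and the starred list at the bottom is class II presentation.

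As a list, class II presentation genes had modestly higher RNA levels in NOD.B10, a call that did not hold in every setting. Of 15 genes, 5 rose and 2 fell, or 9 and 2 adjusted over the list alone. Ciita, the master regulator of class II transcription, rose from 831 ± 20.9 to 1270 ± 28.3 CPM (log2 fold change 0.61, SE 0.0944, adjusted p = 6.32e-04). The costimulatory receptor gene Cd40 rose from 85.8 ± 6.91 to 165 ± 12.5 CPM (log2 fold change 0.95, SE 0.118, adjusted p = 1.05e-04), and H2-DMb2, a peptide loading chain, from 378 ± 34.1 to 527 ± 27.7 CPM. H2-DMb2 lost its call without the first NOD.B10 library (adjusted p = 0.0673). The 2 genes that fell were the costimulatory ligands Cd80 and Cd86, with log2 fold changes of −1.50 and −0.58, and both lost their calls without the first BL/10 library (adjusted p = 0.327 and 0.118), Cd80 also with limma-voom (adjusted p = 0.0615). Camera called the list higher (adjusted p = 0.0416), and adjusted p = 0.439 with an estimated correlation. The call was lost when any 1 of the 4 libraries was left out (adjusted p from 0.0559 to 0.0724), with a replicate block (adjusted p = 0.0592) and with the stricter filter (adjusted p = 0.0538). In the same NOD.B10 libraries 18 of 19 T cell markers were lower. Of 15 class I genes, H2-K1 alone was lower in the test over all genes, with 3 lower adjusted over the list alone (camera adjusted p = 0.644), and H2-K1 lost its call without the second NOD.B10 library (adjusted p = 0.102).

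Several B cell signalling genes rose while their lists as a whole were not called. In the NF-kB list 5 of 22 genes rose and 2 fell, the same numbers adjusted over the list alone. Nfkb2, which encodes p100, rose from 267 ± 48.8 to 424 ± 6.62 CPM (log2 fold change 0.67, SE 0.124, adjusted p = 0.00298), and the chemokine gene Ccl22 fell from 7.28 ± 4.23 to 0.312 ± 0.00167 CPM. The median of this list was 0.28, its mean −0.01 and its upward camera statistic had an adjusted p of 0.092, or 0.0254 without the second BL/10 library. Of 28 B cell receptor signalling genes, Rasgrp3, a Ras activator, rose from 318 ± 45.9 to 565 ± 17.3 CPM, and Lilrb3, counted for Pirb, was also higher. The same 2 were higher adjusted over the list alone (camera adjusted p = 0.0591). The list was called higher with no filter (camera adjusted p = 0.0317), by fry (adjusted p = 0.0465) and by camera without the first BL/10 library. Lilrb3 lost its call without the second NOD.B10 library (adjusted p = 0.18). In the list of BAFF, APRIL and CD40 genes 3 of 13 rose (Cd40, Tnfrsf18 and Traf3) and 2 fell (Tnfrsf9 and Tnfrsf17), both ways of adjusting, with an upward camera statistic (adjusted p = 0.673), a median of 0.08 and a mean of −0.45. Tnfrsf18 lost its call without the first NOD.B10 library (adjusted p = 0.0551), Tnfrsf17 without the first BL/10 library (adjusted p = 0.176), and Traf3 without the first BL/10 library or either NOD.B10 library (adjusted p = 0.0703, 0.0914 and 0.219) and with a replicate block (adjusted p = 0.0511). Of 19 Toll-like receptor pathway genes, Tlr6 rose from 12.5 ± 1.13 to 41.7 ± 0.228 CPM (log2 fold change 1.74, SE 0.159, adjusted p = 6.5e-06) and Tlr12 was also higher, a call lost when any library was left out (adjusted p from 0.082 to 0.251), with DESeq2 (adjusted p = 0.0864) and with a replicate block (adjusted p = 0.0775). Tlr7, a sensor of single-stranded RNA, fell from 125 ± 10.4 to 60.3 ± 0.588 CPM (log2 fold change −1.05, SE 0.118, adjusted p = 3.85e-05). The counts for that list were the same adjusted over the list alone (camera adjusted p = 0.966).

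Camera called the lists of age-associated B cell, marginal zone and B-1 cell, and plasma cell genes lower in NOD.B10. Of 19 age-associated B cell genes 12 fell and 1 rose, or 14 and 1 adjusted over the list alone, with a median of −1.05 (camera adjusted p = 3.66e-05, and adjusted p = 0.439 with an estimated correlation). Itgax of this list also stands in the dendritic cell list. T cell, natural killer cell and dendritic cell markers were lower in the same libraries, and a source in such cells was not tested. S100a6 fell from 13.7 ± 2.33 to 1.33 ± 0.0531 CPM, whereas Fcrl5, an Fc receptor-like inhibitory receptor, rose from 35.7 ± 0.303 to 119 ± 9.69 CPM (log2 fold change 1.74, SE 0.122, adjusted p = 5.34e-07). Of 21 marginal zone and B-1 cell genes 10 fell and 1 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.00356, and adjusted p = 0.439 with an estimated correlation). These included Spn (CD43), 5.52-fold lower, Cd5, 8.8-fold lower, and Myof, 11-fold lower. T cells, whose markers were lower in the same libraries, also express Spn and Cd5. Of 20 plasma cell genes 5 fell and 1 rose, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.627 with an estimated correlation). Among them Pdia4, a folding enzyme of the endoplasmic reticulum, fell from 302 ± 17.8 to 143 ± 1.83 CPM, and the others included Cd28 and Ly6c2, which are not specific to plasma cells. The plasma cell call was lost without the first BL/10 library (adjusted p = 0.125). The 7 B lineage genes Ms4a1, Cd79a, Cd79b, Cd22, Pax5, Cd37 and Ebf1, picked after the data were seen, had log2 fold changes between −0.12 and 0.31. Of these, 0 were called by edgeR, DESeq2 or limma-voom and 1 had an unadjusted p under 0.05.

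The remaining lists of B cell genes were not called. Among 18 naive follicular genes, Fcer2a (CD23) rose from 857 ± 95 to 1270 ± 95.9 CPM and 1 gene was lower, or 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.644). Among 19 germinal centre genes, Il21r was higher and Mki67, Gpr137b and Nek2 were lower, or 2 and 3 adjusted over the list alone (downward camera statistic, adjusted p = 0.907, median 0.06, mean −0.24). Il21r lost its call without the first NOD.B10 library (adjusted p = 0.219). Of 23 chemokine and homing receptors 4 rose and 6 fell, or 4 and 8 adjusted over the list alone (camera adjusted p = 0.673). Ccr6, the receptor for CCL20, rose from 159 ± 21.7 to 355 ± 26.4 CPM (log2 fold change 1.16, SE 0.12, adjusted p = 1.99e-05), and Ccr2 and Selplg fell. Of 18 complement and Fc receptor genes Fcrl5, Fcrl1 and Fcer2a rose and Fcer1g fell, or 4 higher and 1 lower adjusted over the list alone, with an upward camera statistic (adjusted p = 0.907), a median of −0.02 and a mean of −0.01. Fcer1g lost its call without either BL/10 library (adjusted p = 0.0652 and 0.0657). Of 14 cytokine and chemokine genes, Il15 alone was lower by either adjustment (camera adjusted p = 0.639), and it lost its call without the second BL/10 library (adjusted p = 0.0537).

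**Figure D3:**
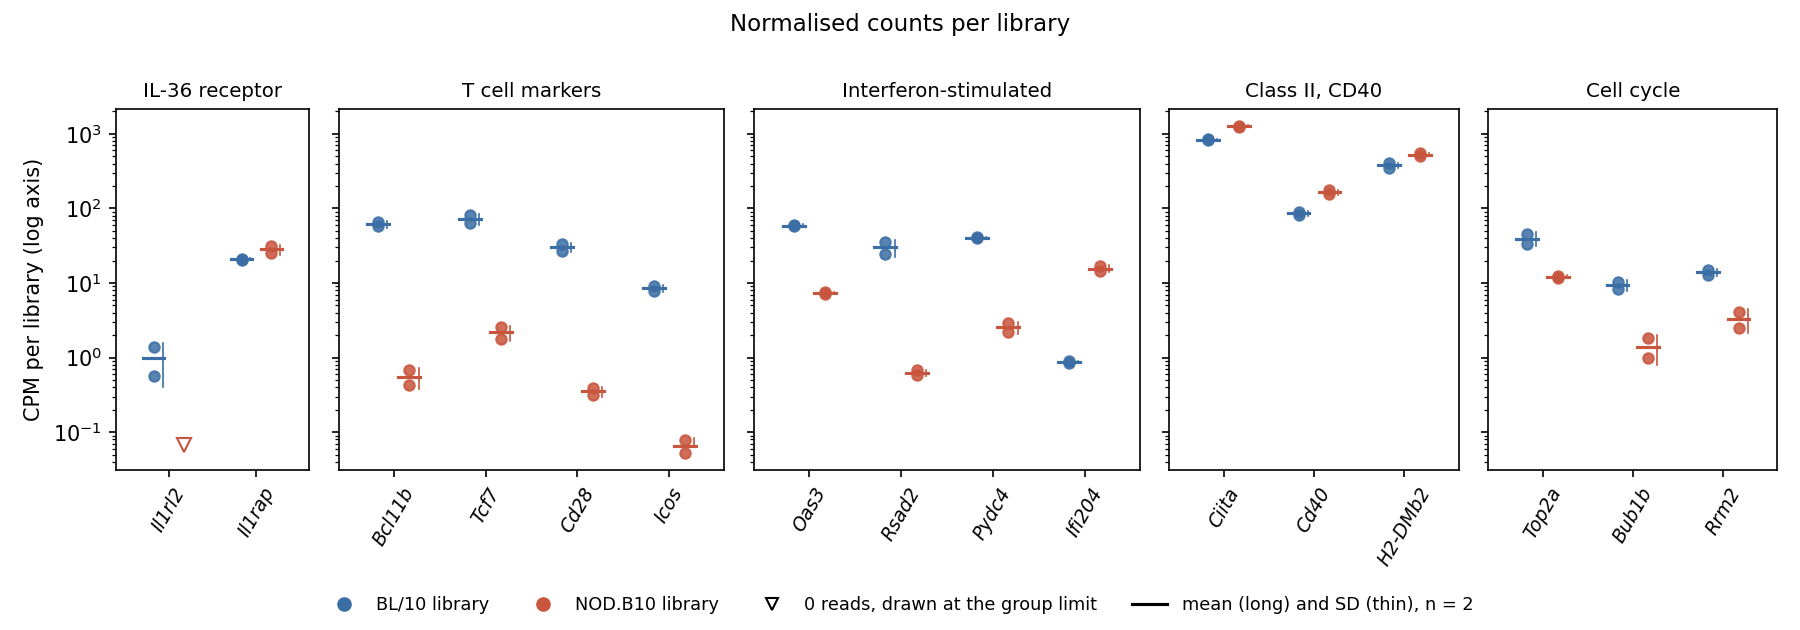
CPM of named genes in each library (log axis), with BL/10 in blue and NOD.B10 in red, the mean as a long line and 1 SD as a thin line (n = 2); a triangle marks 0 reads and is drawn at the level of 3 reads over the group. The libraries of the 2 strains do not overlap for any gene shown. This held for all 1986 called genes and also for Il1rap, which was not called, so it adds nothing to the calls. The mean of Bcl11b is 112-fold lower in NOD.B10.

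Proliferation genes were lower in NOD.B10. Of 34 cell cycle genes 20 fell and 1 rose, or 24 and 1 adjusted over the list alone, with a median log2 fold change of −1.30 (camera adjusted p = 7.69e-09, and adjusted p = 0.439 with an estimated correlation). Top2a, the topoisomerase of dividing cells, fell from 39.4 ± 8.32 to 12.2 ± 0.625 CPM (log2 fold change −1.70, SE 0.183, adjusted p = 2.77e-05). Bub1b, of the spindle checkpoint, was 6.68-fold lower and Rrm2, a subunit of ribonucleotide reductase, 4.22-fold lower. The gene that rose was Tk1, thymidine kinase, with a log2 fold change of 0.91. T cell, natural killer cell and erythroid markers were lower in the same 2 libraries.

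Housekeeping and stress lists showed smaller shifts. Of 43 ribosomal protein genes 11 fell both ways of adjusting, with a median of −0.27 (camera adjusted p = 3.02e-04, and adjusted p = 0.751 with an estimated correlation), and Rps19 fell from 527 ± 52.4 to 281 ± 36 CPM. Of 22 glycolysis and hypoxia genes 4 fell both ways, among them Pdk1, which restrains pyruvate entry into mitochondria, from 116 ± 15.6 to 32.1 ± 5.88 CPM, with Gapdh, Hk2 and Ddit4 (camera adjusted p = 0.00746, and adjusted p = 0.526 with an estimated correlation). Of 10 heat shock genes 4 fell, or 5 adjusted over the list alone: Hspa8, Hspa1a, Hspe1 and Hspa1b (camera adjusted p = 0.0441, and adjusted p = 0.627 with an estimated correlation). Hspa1b lost its call without either BL/10 library (adjusted p = 0.214 and 0.211) and with upper-quartile factors (adjusted p = 0.0513). Without the second BL/10 library the calls of these 3 lists were lost (adjusted p = 0.192, 0.0713 and 0.248), and without the second NOD.B10 library that of the heat shock list (adjusted p = 0.0909), which was also lost with no filter (adjusted p = 0.155) and with the stricter filter (adjusted p = 0.101). In the unfolded protein response list Trib3 and Sdf2l1 rose and Pdia4 and Sec61b fell both ways of adjusting, among 20 genes (camera adjusted p = 0.759). Sdf2l1 lost its call without the first library of either strain (adjusted p = 0.175 and 0.104), and Sec61b without the second BL/10 or the first NOD.B10 library (adjusted p = 0.0734 and 0.141). Of 31 oxidative phosphorylation genes 0 were called by edgeR, DESeq2 or limma-voom and 2 had an unadjusted p under 0.05, with Sdhc at log2 fold change −0.46 (adjusted p = 0.0634). That list was called lower without the first BL/10 library (adjusted p = 2.11e-04) and higher without the second (adjusted p = 0.0394). Of 18 cholesterol synthesis genes 0 were called by the same tools and 4 had an unadjusted p under 0.05, with Mvk at 0.69 (adjusted p = 0.0748).

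Immediate-early genes differed mainly between the NOD.B10 libraries. Of 24 tested, Fosl2 alone was lower, by either adjustment, and it lost its call without the second BL/10 library (adjusted p = 0.0593). The list had a median of 0.22, a mean of 0.31 and a downward camera statistic that was not called (adjusted p = 0.85). Without the first NOD.B10 library the list was called lower (adjusted p = 1.31e-04), and without the second it was called higher (adjusted p = 6.23e-04). Fosb, picked after its values were seen, had 284 CPM in the first NOD.B10 library, 8.66 CPM in the second, and 39.3 and 26.3 CPM in the BL/10 libraries. Among sex-linked genes, Xist stood at 2810 ± 122 CPM in BL/10 and 2170 ± 334 CPM in NOD.B10 (log2 fold change −0.37, SE 0.113, adjusted p = 0.0415), and its antisense partner Tsix was higher, counts that cannot be separated without strand. Xist lost its call without the second BL/10 library (adjusted p = 0.0549) and without the second NOD.B10 library (adjusted p = 0.399), as well as with upper-quartile factors, a replicate block or non-robust dispersion (adjusted p from 0.0564 to 0.0641), and Tsix without the first BL/10 library (adjusted p = 0.155) and without the first NOD.B10 library (adjusted p = 0.0676). The 4 Y-linked genes of the list did not pass the filter.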

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

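Of the alternatives, removal of Rn45s was chosen only after the result was seen, and so were 33 of the genes followed here. The count of called genes stayed within 1.5 times the 1986 reported in every alternative run, from 1544 with the stricter filter, which tested 10904 genes, to 2584 without a filter, which tested 17058. Other normalisations and tools called 1961 (RLE), 1947 (upper quartile), 1934 (DESeq2), 1894 (limma-voom) and 1947 (non-robust dispersion) genes, removal of the immunoglobulin genes 1986 and of Rn45s 1989. Leaving out each library called 1758 to 2199 genes, 586 to 993 of them higher and 1010 to 1228 lower, in fits where the lone library of a strain is assumed to vary like the pair of the other. None of the 1986 calls changed sign in any of these alternatives where the gene was tested. With the replicate number as a block, 1802 genes were called, of which 1729 were among the 1986, and 18 lists. Deviations of same-numbered libraries had a correlation across genes of −0.017, so no shared effect of the numbers was visible. Whether the samples were handled in pairs cannot be told from this value. Of 97 called genes named by the rule, 76 kept their call wherever they were tested and 21 lost it under at least 1 alternative, with 12 lost without the second BL/10 library, 8 without the first, and 7 without each NOD.B10 library; the stricter filter left 20 untested. Of the 33 genes picked later 15 were called and 10 of these lost the call somewhere. Camera called 17 lists, and between 14 and 18 under the other normalisations, no filter, dispersions, gene removals and left-out libraries. The stricter filter called 11 of the 29 lists it could test. With an estimated correlation camera called 0 lists, with 3 at an unadjusted p under 0.05, while fry, which asks a different question of each list, called 9. The estimated setting has few residual degrees of freedom, so hardly any list could pass it.

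Leaving out a library gave a call against the reported direction for 2 lists and 3 of the genes followed here, none of them called with all libraries, and the cause was not tested. Other lists that were not called also turned direction, without a call. For the immediate-early list the adjusted p ran from 1.31e-04 (called lower, without the first NOD.B10 library) to 0.962 (without the second BL/10 library), with an upward call at 6.23e-04 without the second NOD.B10 library. For oxidative phosphorylation it ran from 2.11e-04 (called lower, without the first BL/10 library) to 0.816 (without the second NOD.B10 library), with an upward call at 0.0394 without the second BL/10 library. Fos had log2 fold changes from −1.84 to 2.58, Fosb from −1.93 to 3.11 and Dusp1 from −1.45 to 2.03, each called lower without the first NOD.B10 library and higher without the second. With 2 libraries per strain, simulated changes of 1.5-fold were recovered in 30% of genes. That simulation made 207 calls against 1986 in the data, so its cut on the unadjusted p was stricter and the share may differ here. Small differences can still have been missed.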

Other observations

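Every test in this part except the counts of adjacent gene pairs was chosen only after the result was seen, and so were the genes and windows described here.

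Apobec3, a cytidine deaminase that restricts retroviruses, fell from 601 ± 15.4 to 40.7 ± 0.944 CPM (SD, n = 2, log2 fold change −3.88, edgeR adjusted p = 1.26e-10). Ly6a, which encodes the surface antigen Sca-1, fell from 229 ± 45.8 to 24.5 ± 0.673 CPM (log2 fold change −3.22, edgeR adjusted p = 3.15e-08), and Ly6e, of the interferon-stimulated list, fell from 1672 ± 221 to 418 ± 18.9 CPM. In a window on chromosome 15 from 74000001 to 76000000 that holds the Ly6 cluster, 13 of 27 tested genes were lower. The window on chromosome 7 from 104000001 to 106000000, with Trim12a and related Trim genes, had 9 lower and 3 higher genes among 21. On chromosome 19 from 34000001 to 36000000, with the Ifit genes of the interferon-stimulated list, 6 of 12 were lower, and on chromosome 1 from 60000001 to 62000000, with Cd28 and Icos, 5 of 10 were lower and 2 higher. Reads shared among members of the Ly6, Trim and Ifit families leave their single counts uncertain.

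Some genes differed between the libraries of a strain. Rag1, of the antigen receptor recombinase, had 87.1 CPM in the first BL/10 library, 2.17 CPM in the second and 0 reads in NOD.B10 (edgeR adjusted p = 0.559). Dntt had 10.6 and 0.62 CPM and Arpp21 7.67 and 0.62 CPM in the BL/10 libraries, each with 0 reads in NOD.B10. Igj, the immunoglobulin joining chain, had 608 and 119 CPM in BL/10 and 14 and 7.21 CPM in NOD.B10. The salivary genes Bpifa2 and Amy1 had 322 and 177 CPM and 69.3 and 46.7 CPM in BL/10, against 7.52 and 29.8 CPM and 2.38 and 14.1 CPM in NOD.B10. Rprl3, a ribonuclease P RNA-like gene, had 0 and 0.0388 CPM in BL/10 and 122 and 39.4 CPM in NOD.B10. Fos had 228 CPM in the first NOD.B10 library and 10.7 CPM in the second, and Dusp1 83.9 and 7.56 CPM. Rn45s took 2.11% and 4.1% of the reads in BL/10 and 1.18% and 1.69% in NOD.B10.

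T cell markers were far lower in NOD.B10, although the cells were sorted as B cells, a step that would remove T cells. Of the 19 markers, 94.7% were called lower, on 11 chromosomes, and 1 of the 19 also stands in another list. The most abundant members in BL/10 were Cd2, at 205 CPM against 159 CPM in NOD.B10, Tcf7, at 71.9 CPM against 2.17 CPM, and Lck, at 70.0 CPM against 42.1 CPM. The median of the macrophage markers lay 4.66 log2 units above that of the T cell markers (two-sided permutation p = 0.0001, over genes and not libraries). Dendritic cell (−0.92), neutrophil (−2.30) and stromal (0.22) medians also lay above it. Those of natural killer (−4.62), helper and regulatory T (−4.52), mast (−3.97) and erythroid cells (−5.62, zeros at their bound) lay nearer the −5.30 of T cells. Expression of some markers by B cells would shrink their folds, so unequal medians do not decide. A lower share of B cell RNA in BL/10, which would raise markers of every other type, stays open. More T cell RNA in the BL/10 libraries also stays open, because the share of markers called lower restates the pattern. Whether the sort or the nodes of the strains differed was not tested.

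Interferon-stimulated genes were lower in NOD.B10 in the same libraries. The median log2 ratio of the excess over NOD.B10 in the second BL/10 library to that in the first was −0.15 for 37 interferon-stimulated genes and 0.32 for 18 T cell markers, a difference of −0.47 (two-sided permutation p = 0.008) that rests on 2 libraries. The T cell markers did not share 1 ratio, running from −0.35 to 1.06, so T cell RNA as the only source of the excess stays open. The share of the list called lower was 9.0 times that of other genes (75.5% against 8.4%, Fisher's exact p = 8.4e-30), on 15 chromosomes. Separate strain variants or lost alignments, with no shared cause and as frequent as in other genes, would give a share near theirs. These values argue against that case only. Whether such variants or losses were more frequent in this list was not tested, so they stay open as a source. Fisher's test also counted neighbouring family members, such as the Ifit genes, as separate genes. In single genes of the list they stay open. A difference between the strains in interferon response and a source in other cell types were not tested.

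Called genes lay next to each other on the chromosomes more often than random placement gives, with 347 adjacent pairs called in the same direction against a mean of 152.5 in 10000 permutations (p = 0.0001, the smallest they can give), which is consistent with strain haplotype blocks. Without pairs that overlap or share the start of their symbols 257 pairs stayed, against a mean of 127.5 (permutation p = 0.0001). Family members under unlike symbols were not removed, such as Ifit1 and its neighbour I830012O16Rik, counted for Ifit3b. Reads shared by overlapping or like-named neighbours were thus not the whole source, but other shared reads stay open. Reads of NOD.B10 lost against the reference were not the only source, because 99 of the pairs kept in this way were called higher, against a mean of 46.1 (permutation p = 0.0001). On chromosome 17 from 33996012 to 35267497, the H2 interval that both strains may share, 9.7% of 72 tested genes were called against 15.2% elsewhere (Fisher's exact p = 0.25), too few genes for this to be told apart from chance. Neighbouring genes with common regulation stay open.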
